A study of Arabidopsis thaliana with 4 samples.

How the data were processed

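The series holds small RNA libraries from unopened flower buds of Arabidopsis thaliana Columbia, 1 library for each of wild type, ddm1 (the ddm1-2 allele), rdr6 (rdr6-15) and the double mutant. Per the labels' protocols, RNA was extracted with Trizol, enriched for small RNA with a mirVana kit and made into libraries with a TruSeq small RNA kit. Each deposited file lists distinct sequences with their raw read counts, not normalized, as its values show. Bowtie and the TAIR10 build are named in the submitters' processing notes, with no version or setting, and adapter trimming and filters are not given in the sources used here. Every deposited sequence was 18 to 28 nt long and had a perfect site in the reference, so reads without a perfect site play no part. No molecular identifiers were used, so copies made by PCR count as separate reads.

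All 1993523 distinct sequences were placed at each of their perfect sites on both strands of the TAIR10.1 reference with an exact search written in Python 3.11.15 with numpy 2.4.6 and numba 0.67.0. They had 6154822 sites, with at most 879 for a single sequence. A read with several sites gave each an equal part of its count. Levels (RPM) are read counts scaled to all deposited reads of the library. Reads matching ribosomal, transfer, small nuclear or small nucleolar RNA, or an organelle genome, were left out of locus and window counts but kept in the totals. The nuclear ribosomal repeat was taken from the start of the small subunit gene to 4000 nt beyond the last annotated gene of the unit, because its large subunit is not annotated.

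The reference carries no transposon annotation, so the fallback fixed in the plan was used. Transposons were represented by 35946 nuclear windows of 1000 nt that overlap no annotated gene, which cover 30.2% of the nuclear genome. Pseudogenes were allowed in these windows, and 12844 of them hold a pseudogene without a description, a class that makes up 4343 of the 4851 annotated pseudogenes. Pericentromeres were the bins of 100 kb in which protein-coding genes, introns included, cover less than 25%, 18.6 Mb in all with 15626 gene-free windows. Families were assigned to nuclear pseudogenes by the best tblastx 2.17.0 match (E value at most 1e-20), or by annotation as Sadhu. Queries were genes annotated as CACTA, Copia, LINE, Mutator or hAT elements and sequence within 3000 nt of the 12 perfect siR854 sites. Long-known active elements were added by hand, namely EVD (AT5G17125) and AT1G11265 for Copia, AT2G12210 for CACTA and AT4G08680 for Mutator. This family assignment was chosen after the reference had been seen, and the siR854-related group is defined by similarity and need not hold a single family. Gypsy, Helitron and Mariner groups that the plan named are not annotated and were not analysed here.

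With 1 library per genotype no test between genotypes was possible. Ratios carry an exact conditional (Clopper-Pearson) 95% interval and shares a Wilson interval, from scipy 1.17.1, and tables were handled with pandas 2.3.3 and figures drawn with matplotlib 3.10.9. These intervals describe the reads of 2 libraries, not the genotypes. Loci were compared by size alone, as at least 4-fold higher or lower among loci with at least 100 reads of 21-22 nt in either library. A library under 3 reads was set to 3 reads for this rule, and a ratio against 0 reads is given as a lower bound from those 3 reads. For values of 1 to 3 reads the ratio of the counts is given with its interval, and a shared count below 1 read is set to 3 reads. The comparisons were ddm1 over wild type, rdr6 over wild type, double mutant over ddm1 and double mutant over rdr6. Part of a read count at a gene that shares sequence with near-identical copies is uncertain, as is the assignment between genes that overlap.

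The following choices were made before the data were examined. The named genes were all TAS loci, DDM1 and RDR6, every miRNA with at least 1000 reads in a library, and the 10 loci with the largest increase and the 10 with the largest decrease in each of the first 3 comparisons, leaving out structural and MIR genes. Members of fixed lists serve as examples. The 9 gene lists were TAS loci (8), PPR genes (20), auxin receptors (4), tasiRNA targets (6), NBS-LRR genes (10), silencing machinery (21), epiallele genes (5), known active transposons (9) and abundant messenger RNAs (7), besides 36 mature miRNAs. A list member was measured where either library had at least 20 reads, and the median log2 ratio of a list was set among 10000 random lists of the same size matched on abundance in 10 bins, as a description of these libraries. Other settings fixed in advance were single-site reads alone, the whole count at every site, denominators of nonstructural reads or of listed miRNA reads, reads lying wholly within a locus, 21 nt or 22 nt alone, a minimum of 20 reads, a 2-fold rule and other definitions of the shares. Pseudogenes in place of windows, windows without pseudogenes and the families under every setting were added after the data had been seen.

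The size rule was tested on simulated read counts per locus, drawn from the real levels with counting error alone. Sharing of reads between sites and variation between libraries were not simulated. Recovery was likely from the start, since the simulated changes were larger than the 4-fold rule. For ddm1 over wild type, 98.0% of 99 loci changed 8-fold and 99.0% of 100 loci changed 16-fold were recovered among 441 tested. For rdr6 over wild type all of 26 and 28 such loci were recovered among 215 tested, and for the double mutant over ddm1 all of 96 and 98 among 457. The site search gave the same sites as a plain text search for 2000 sequences, and the ratio interval covered the true value in 96.4% of 2000 draws.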

Results

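Small RNAs of 18 to 28 nt were sequenced from unopened flower buds of Arabidopsis thaliana Columbia plants of 4 genotypes that were grown side by side. The genotypes were wild type, ddm1 (labelled as generation F6), rdr6 and the ddm1 rdr6 double mutant (labelled without a generation), with 1 library each. DDM1 is a chromatin remodeller that keeps transposons methylated and silent, and RDR6 is an RNA-dependent RNA polymerase that makes double-stranded RNA for secondary small interfering RNAs (siRNAs). The libraries held 3129843 reads in wild type, 3528426 in ddm1, 2677800 in the double mutant and 1479287 in rdr6, and 3 reads, the smallest level counted as present, equalled 0.959, 0.850, 1.12 and 2.03 RPM (reads scaled to the library total). Because each genotype had 1 library, no difference given here had a replicate check, and all intervals are 95% intervals that cover counting error only. The title of the series names RDR6-dependent RNA-directed DNA methylation. The comparisons therefore asked which transposon siRNAs were higher in ddm1 and which of them were lower where RDR6 was also missing.

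The ddm1 library had a larger share of 21 nt and a smaller share of 24 nt reads than wild type, and in the double mutant both shares lay on the other side of wild type. Scaled to miRNA reads, the 24 nt level of ddm1 and the 21 nt level of the double mutant were above wild type. The 21 nt share was 21.4% in wild type, 35.35% (Wilson interval 35.30% to 35.40%) in ddm1, 16.5% in the double mutant and 21.4% in rdr6. The 24 nt class, the usual product of RNA polymerase IV and DCL3, made up 46.1% (46.0% to 46.1%) of wild-type reads, 41.3% of ddm1 reads, 58.8% of double mutant reads and 49.3% of rdr6 reads. The 22 nt share differed less, at 7.33%, 9.28%, 7.94% and 7.49% in the same order. Reads with more than 10 perfect genomic sites were 3.5002% of the wild-type library, 17.0% of ddm1, 5.82% of the double mutant and 3.40% of rdr6. Reads of structural RNAs and organelles were 10.2%, 6.41%, 5.88% and 12.6%, and exact sequences of the 36 listed miRNAs were 17.0%, 13.2%, 10.9% and 15.6%. The sequence miR166a alone gave 372465 of these 530555 miRNA reads in wild type and 351050 of 465111 in ddm1. It gave 147702 of 292823 in the double mutant and 180013 of 230738 in rdr6. Scaling to miRNA reads therefore rests largely on this sequence, and a miRNA denominator without it was not tried.

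**Figure D1:**
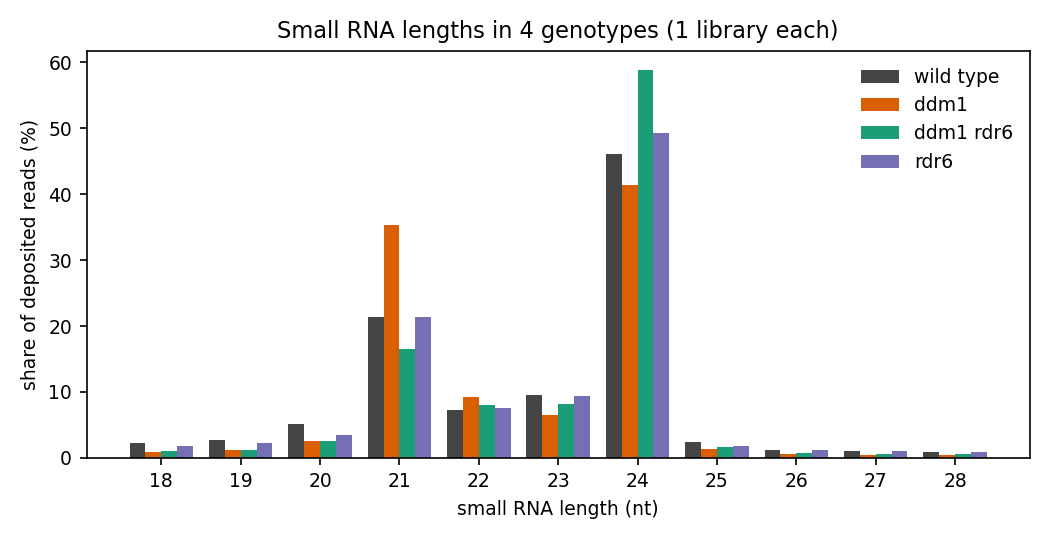
Share of all reads (percent, linear axis) at each length from 18 to 28 nt in the 4 libraries, 1 bar per genotype. The ddm1 library peaked higher at 21 nt (35.35%) than the others (16.5% to 21.4%), and the double mutant was highest at 24 nt (58.8%).

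The mutated genes themselves gave almost no small RNA. DDM1 (AT5G66750, chromosome 5, 26648897 to 26653191, TAIR10.1 build) had 0 reads of 21-22 nt in all 4 libraries. RDR6 (AT3G49500, chromosome 3, 18348974 to 18353673) had 0 reads in wild type, 1 in ddm1, 25 in the double mutant and 6 in rdr6. In the double mutant these reads lay in coding sequence on both strands (48.0% on the plus strand), with the middle 90% between 18352823 and 18352875. Small RNA reads do not measure the messenger RNA of either gene, so the trans-acting siRNA (TAS) loci, whose siRNAs need RDR6, served as the check of the rdr6 labels.

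In both rdr6 libraries the TAS siRNAs were nearly gone. Their 21-22 nt reads summed to 4645 RPM in wild type and 4886 in ddm1, against 32.1 in rdr6 and 21.7 in the double mutant, a log2 ratio of -7.18 (-7.60 to -6.75) for rdr6 over wild type and -7.82 (-8.21 to -7.45) for the double mutant over ddm1. All 7 measured TAS loci were at least 4-fold lower in each comparison. TAS1C (AT2G39675, chromosome 2, 16537288 to 16538277) gave 2917 RPM in wild type and 6.76 in rdr6, 431.5-fold lower (235 to 900.2). TAS2 (AT2G39681, chromosome 2, 16539384 to 16540417) was 140.4-fold lower (68.0 to 349.6), TAS3A (AT3G17185, chromosome 3, 5861491 to 5862437) 50.3-fold (30.4 to 90.2) and TAS3B (AT5G49615, chromosome 5, 20134200 to 20134786) 32.5-fold (17.0 to 71.3). TAS1A (AT2G27400) was 17.2-fold lower (7.24 to 53.6) and TAS1B (AT1G50055) 278-fold (57.5 to 1722), while TAS3C (AT5G57735), with 0 reads in rdr6, was at least 5.04-fold lower. TAS4 (AT3G25795) had 16 reads in wild type, 1 in ddm1 and 0 in both rdr6 libraries. All of these reads lay in exons of the noncoding TAS transcripts. The median log2 ratio of the list was -5.65 in rdr6 over wild type, below all of 10000 random lists matched on abundance (random median -0.05). In the double mutant over ddm1 it was -7.15, at the 14.1th percentile of random lists (random median -2.99). In ddm1 over wild type the list median (-0.10) and the summed reads (1.05-fold, 1.03 to 1.08) differed in sign, and the median lay at the 0.680th percentile of random lists (random median 4.79). The 24 nt reads of TAS loci followed the same order, with 484 RPM in wild type, 900 in ddm1, 1.49 in the double mutant and 2.03 in rdr6.

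Pentatricopeptide repeat (PPR) genes, a known source of phased secondary siRNAs, showed the same pattern as TAS loci. Of the 13 measured in rdr6 against wild type, 12 were at least 4-fold lower, and all 15 measured in the double mutant against ddm1 were. Their summed 21-22 nt reads were 340 RPM in wild type, 440 in ddm1, 3.73 in the double mutant and 4.51 in rdr6, a log2 ratio of -6.24 (-7.49 to -5.12) for rdr6 over wild type. AT1G63150 (chromosome 1, 23419294 to 23421714, all reads in coding sequence) had 173.8 reads in wild type and 0.643 of a shared read in rdr6, 27.4-fold lower with rdr6 set to 3 reads, and AT1G62910, with 1.14 reads in rdr6, was 64.7-fold lower (13.0 to 2931). List medians were -3.31 and -3.81 in the same comparisons, below all random lists, and 0.41 in ddm1 over wild type (28.7th percentile). AFB3, an auxin receptor gene, had 34.5 reads in wild type, 26 in ddm1, 1.5 in the double mutant and 1 in rdr6, and ARF4, a tasiRNA target, had 36, 45, 1 and 1. These were the only measured members of their lists, and both were at least 4-fold lower in each rdr6 library.

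In ddm1, 21-22 nt siRNAs were many times more abundant in the pericentromeres than in wild type. Reads of this class in gene-free windows, the stand-in used for transposons, amounted to 51145 RPM in wild type and 232550 in ddm1, a ratio of 4.55 (4.52 to 4.57). Pericentromeric windows carried the difference, at 20323 and 201834 RPM (ratio 9.93, 9.85 to 10.01; with single-site reads 12565 and 34810 RPM), while windows on the arms held 30824 and 30718 (ratio 0.997, above 1 when scaled to miRNA reads). With reads of a single genomic site alone the log2 ratio over all gene-free windows was 0.59, against 2.18 with shared counts. Windows without a pseudogene held 35892 RPM of 21-22 nt in wild type and 63584 in ddm1. With single-site reads their direction turned, at 26132 and 24018 RPM. The 24 nt class differed by region. It was 1.39-fold (1.38 to 1.40) of wild type in the pericentromeres, a direction that turned with single-site reads (70736 RPM in wild type and 68599 in ddm1), and 0.759-fold (0.756 to 0.762) on the arms, and over all windows its log2 ratio was -0.01, which became 0.35 when scaled to miRNA reads and 1.36 when each site counted the whole read. Every log2 ratio of ddm1 over wild type shifts by 0.36 under the miRNA denominator and by -0.06 when structural reads are left out.

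**Figure D2:**
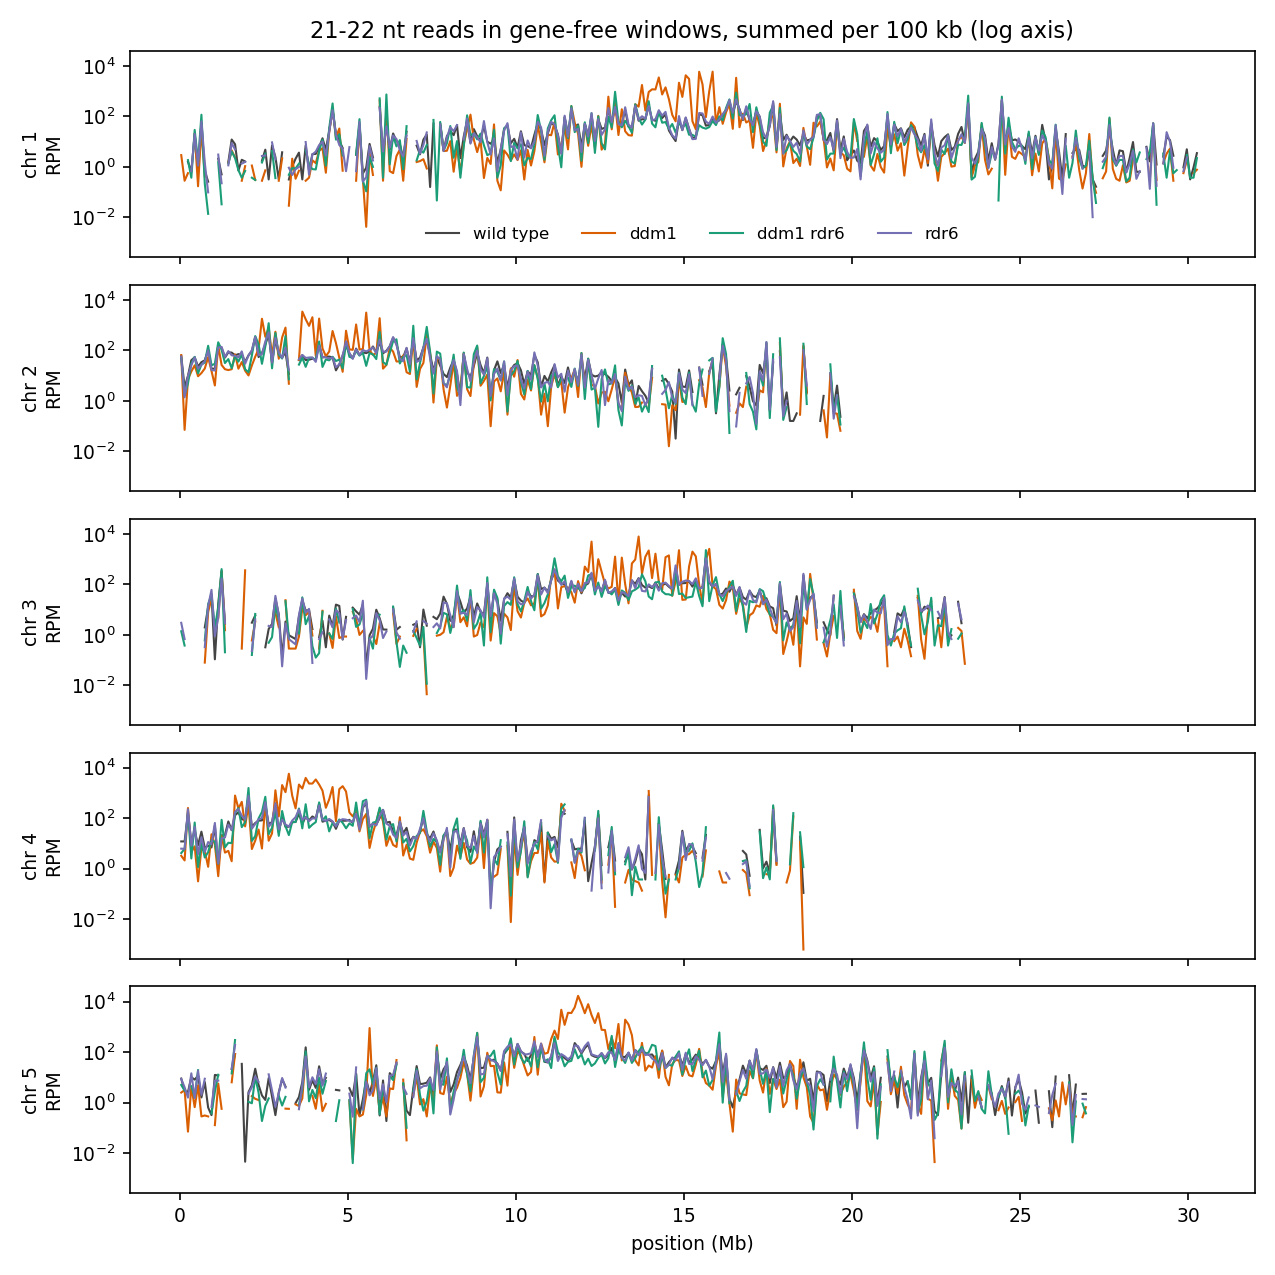
RPM of 21-22 nt reads in gene-free windows, summed in bins of 100 kb (log axis, gaps where no read fell), along the 5 chromosomes (position in Mb), with 1 line per library. The ddm1 line stood above the others around the centromeres, where pericentromeric windows held 201834 RPM against 20323 to 21976 in the other 3 libraries.

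Of the 1025 gene-free windows with at least 100 reads in ddm1 or wild type, 783 were at least 4-fold higher and 53 at least 4-fold lower in ddm1; with single-site reads 200 were higher, and with the whole read at every site 2513. Among annotated loci, 273 of 316 tested pseudogenes were at least 4-fold higher and 12 at least 4-fold lower. Among 114 tested protein-coding genes 12 were higher, 29 lower and 73 between, with a median log2 ratio of -0.07. Summed over all coding genes the 21-22 nt class was 25380 RPM in wild type and 16198 in ddm1 (ratio 0.638, 0.631 to 0.645). AT3G06435, chosen after its values were seen, made up much of this difference, with 4116 and 334 RPM. Across the 288 loci that were higher, the median 24 nt log2 ratio was 1.13, with 101 at least 4-fold higher and 25 at least 4-fold lower at 24 nt.

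The family related to siR854, a small RNA whose perfect sites lie in Athila-type LTR retrotransposons, held the largest difference of the 8 groups. Its 638 pseudogenes gave 3285 RPM of 21-22 nt in wild type and 146648 in ddm1 (ratio 44.6, 43.8 to 45.5; log2 5.48, and 4.22 with single-site reads), and 196 of its 198 tested loci were at least 4-fold higher. The siR854 sequence itself had 0 reads in all 4 libraries. CACTA DNA transposons were 10.6-fold higher at 21-22 nt (9.86 to 11.3), from 281 to 2968 RPM, and 2.25-fold higher at 24 nt, with log2 ratios of 1.92 and 0.54 from single-site reads and 5.21 and 2.15 from whole counts at every site. Copia retrotransposons were 2.92-fold higher at 21-22 nt (2.79 to 3.06) and 4.67-fold lower at 24 nt (log2 0.82 and -2.66 with single-site reads, and -0.71 at 24 nt with whole counts). The higher Copia level lay mainly in 21 nt reads, as 22 nt reads alone were near their wild-type level. Mutator elements were lower in both classes, 2.62-fold at 21-22 nt and 6.11-fold at 24 nt, as were hAT elements, 2.497-fold and 2.92-fold. With whole counts at every site the log2 ratios shrank to -0.09 and -1.36 for Mutator and to -0.11 and -0.51 for hAT, and with single-site reads Mutator at 21-22 nt was at -2.23. LINE elements were 0.807-fold at 21-22 nt, a direction that turned when scaled to miRNA reads (log2 0.05), and Sadhu elements lay at 1.07-fold with an interval that held 1 (0.872 to 1.32).

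**Figure D3:**
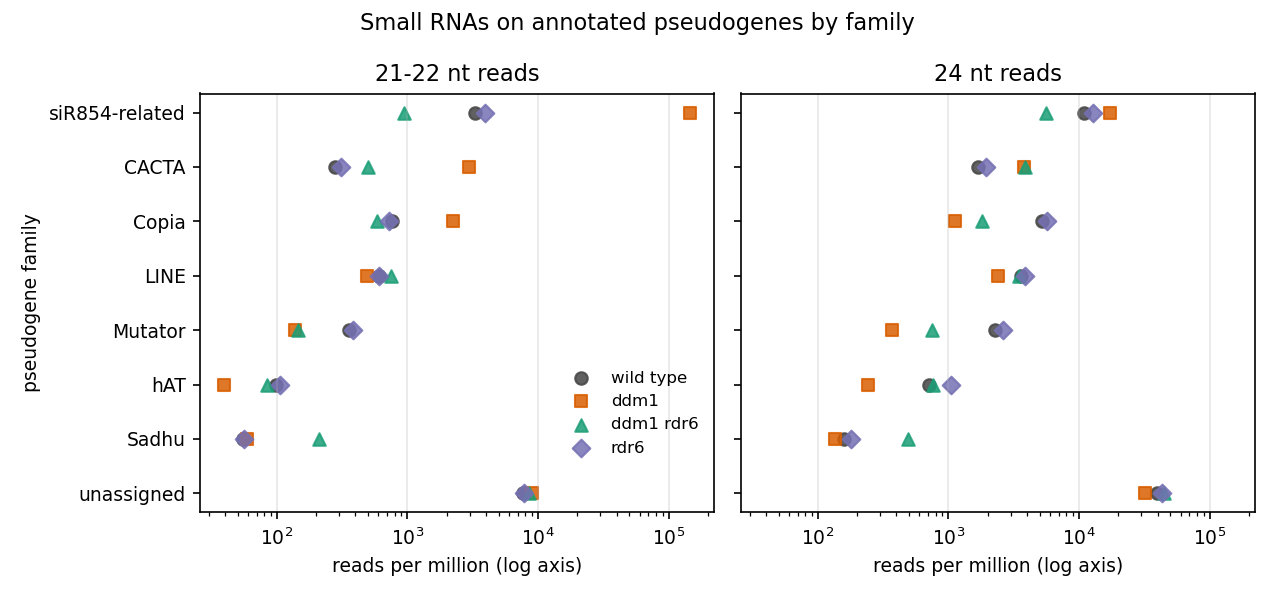
RPM (log axis, 21-22 nt on the left and 24 nt on the right) on pseudogenes of each transposon family, 1 point per library. The siR854-related family stood at 146648 RPM of 21-22 nt in ddm1 and at 948 to 3927 in the other libraries; LINE 21-22 nt, Sadhu 24 nt and unassigned 24 nt reads lay below wild type in ddm1 but above it when scaled to miRNA reads.

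EVD (AT5G17125, chromosome 5, 5630538 to 5634764), a Copia element known to transpose when methylation is lost, gave 1.44 RPM in wild type and 885 in ddm1, 615-fold higher (270.1 to 2543), with its reads in the annotated exon. The related AT1G34967 (chromosome 1, 12755620 to 12759846) was 381-fold higher (167 to 1576). Only 59 of its 1934 ddm1 reads had a single site, against 1246 of 3122 for EVD, so its ratio rests mainly on reads shared with other copies. The other 8 of the 10 largest differences were siR854-related pseudogenes, led by AT4G06664 (chromosome 4, 3869799 to 3871808; 1.59 and 1086 RPM, 682-fold, 291 to 2095), AT3G32210 and AT4G06712. In the same order, 582 of 3832, 202 of 2428 and 57 of 3584 ddm1 reads had a single site, while AT1G37603 had 4611 of 6685. Loci that share most of their reads with copies are not separate observations. Of 9 elements listed beforehand as known to be active, 3 were measured. EVD and CACTA1 (AT2G12210, 11.1-fold, 4.47 to 35.1) were higher, AtMu1 (AT4G08680) was 7.001-fold lower (3.08 to 21.2), and the median log2 ratio of 3.47 lay at the 84.5th percentile of random lists. At 24 nt AtMu1 had 148 RPM in wild type and 0.236 in ddm1.

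A smaller set of 46 loci, of which 29 were coding genes, was at least 4-fold lower in ddm1 than in wild type. AT2G16018 (uncharacterized, chromosome 2, 6972222 to 6973705) had 115.8 RPM in wild type and 1 read in ddm1, 409-fold lower (72.8 to 16163), and its neighbour AT2G16030, a methyltransferase-like gene (6973673 to 6975007, 92.3% of wild-type reads in coding sequence), was 71.3-fold lower (37.3 to 157). AT5G27606 (chromosome 5, 9752002 to 9753404; 60.4% of wild-type reads coding and 39.6% intronic) was at least 127-fold lower, AT5G28560 at least 69.9-fold and AT2G04062 at least 52.0-fold, each with 0 reads in ddm1. AGL36 (AT5G26650, chromosome 5, 9343785 to 9345011), an imprinted MADS-box gene, had 51.1 RPM in wild type and 1 read in ddm1, and PUM25, AT1G09485, AT4G04250 and AT3G43833 completed the 10 lowest. The 46 loci that were at least 4-fold lower had a median 24 nt log2 ratio of -3.67, and 38 of them were at least 4-fold lower at 24 nt too.

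In plants with DDM1, summed siRNAs of gene-free windows without RDR6 were near their wild-type level. Gene-free windows held 52278 RPM of 21-22 nt in rdr6, 1.02-fold of wild type (1.01 to 1.03), and 315492 RPM of 24 nt, 1.10-fold (1.10 to 1.11). The 21-22 nt log2 ratio of 0.03 became -0.23 when each site counted the whole read. No tested pseudogene of 33 differed by 4-fold, and the siR854-related family stood at 1.20-fold (1.16 to 1.23). The largest family difference was that of hAT elements at 24 nt, 1.48-fold (1.38 to 1.58). Copia at 21-22 nt (0.946-fold, 0.879 to 1.02) and LINE (0.987-fold, 0.911 to 1.07) had intervals that held 1, and both turned above 1 when scaled to miRNA reads.

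The loci that differed by 4-fold in rdr6 were all genes. Of 158 tested, 17 were at least 4-fold lower, 8 coding genes and 9 noncoding genes, and 1 was higher. Besides TAS and PPR loci they included CHX18 (AT5G41610, chromosome 5, 16638302 to 16641933), a cation exchanger gene, with 182 RPM in wild type, 69.2 in ddm1, 1.12 in the double mutant and 1 read in rdr6, all wild-type reads in coding sequence. The noncoding gene AT5G41612 overlaps CHX18 on the other strand and shares these reads. AT5G05905, a noncoding RNA gene on chromosome 5 (15757451 to 15757709), gave 88.5 RPM in wild type, 488 in ddm1, 1.12 in the double mutant and 1.35 in rdr6 (65.5-fold lower than wild type, 18.0 to 543). Only 3.97% of its wild-type and 1.10% of its ddm1 reads lay on its own strand. In ddm1 the middle 90% of read midpoints lay at 15757696 to 15757697, and reads ran past the gene end to 15757730. The gene that was higher was AT4G10800 (chromosome 4, 6643189 to 6645530), at 16.0 RPM in wild type, 115.9 in ddm1, 1.49 in the double mutant and 136 in rdr6 (8.51-fold, 6.21 to 11.8). The sequence ACAATAATGACTCTGAGGACT, 21 nt long with 1 site at 6645432 to 6645452 on the minus strand of the untranslated exon, made up 87.1% of its reads in rdr6. The other 9 of the 10 highest loci were between 1.51-fold (AT1G38450) and 1.80-fold (AT3G01845).

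In the ddm1 background, gene-free windows held fewer 21-22 nt siRNAs where RDR6 was also missing, and the size of the difference depended on reads with several sites. With shared counts they held 60684 RPM in the double mutant against 232550 in ddm1, a log2 ratio of -1.94 (-1.95 to -1.93). In the pericentromeres the difference was 9.18-fold, from 201834 to 21976 RPM, while on the arms the double mutant stood 1.26-fold higher (1.25 to 1.27). With single-site reads, all gene-free windows held 44737 RPM in the double mutant, 53178 in ddm1 and 35367 in wild type, a log2 ratio of -0.25. In the same order the pericentromeres held 13177, 34810 and 12565 RPM and the arms 31568, 18369 and 22804, so the surplus of ddm1 over wild type lay in the pericentromeres, while the arms were lower in ddm1 (above wild type when scaled to miRNA reads). Of the 783 windows that were 4-fold higher in ddm1, 735 (93.9%) were at least 4-fold lower in the double mutant, 11 differed from ddm1 by less than 1.5-fold, and 673 came to at most 2-fold of wild type. Because the 783 were chosen for a high ddm1 value and ddm1 is also the denominator, part of this share can arise by construction. Windows that share reads with copies are not separate observations. Every log2 ratio of the double mutant over ddm1 shifts by 0.27 under the miRNA denominator. The largest part of that denominator, miR166a, was 0.554-fold of ddm1, while several other listed miRNAs were higher in the double mutant. The ddm1 line is labelled as generation F6 and the double mutant without a generation. For all values of the double mutant over ddm1, loss of RDR6 and a separate history of the lines therefore cannot be told apart.

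The siR854-related family stood at 948 RPM in the double mutant against 146648 in ddm1, 155-fold lower (log2 -7.27, and -6.25 with single-site reads) and also below the 3285 RPM of wild type, with 196 of 198 tested loci at least 4-fold lower. All 10 loci with the largest decrease belonged to it, ranked with values under 3 reads set to 3. They ran from AT1G40119 (chromosome 1, 15187719 to 15189614, 2441 and 1.16 RPM, 2110-fold, 745 to 10566) to AT1G37603 (1895 and 0.537 RPM). By unchanged counts AT1G37603 was 3529-fold lower (910 to 200418). Of ddm1 reads, 452 of 8612 at AT1G40119 and 4611 of 6685 at AT1G37603 had a single site. CACTA elements were 5.99-fold lower and Copia elements 3.80-fold lower at 21-22 nt, with log2 ratios of -2.10 and -1.26 from single-site reads and -3.78 and -1.50 from whole counts, and EVD had 18.4 RPM, 48.0-fold less (36.5 to 65.5). Mutator elements, low in ddm1, were 1.07-fold of ddm1 (0.931 to 1.22), and Sadhu elements were higher, at 211.8 against 58.8 RPM. Unassigned pseudogenes were 0.949-fold, a direction that turned when scaled to miRNA reads (log2 0.19).

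**Figure D4:**
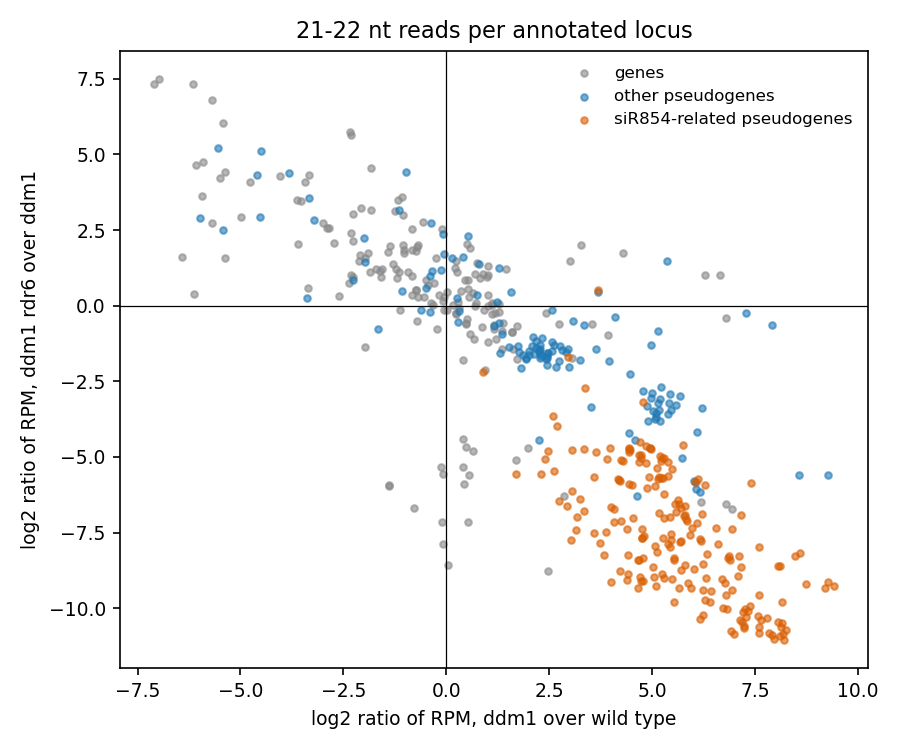
Log2 ratio of 21-22 nt reads in ddm1 over wild type (horizontal axis) against the double mutant over ddm1 (vertical axis), 1 point per tested annotated locus, with genes in gray, siR854-related pseudogenes in orange and other pseudogenes in blue. Points of the siR854-related family lay at the lower right (medians 5.44 and -7.69), and part of the downward slope arises by construction because both axes share the ddm1 library with opposite sign.

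The 24 nt class took another course in the double mutant. Over gene-free windows it was 1.37-fold of ddm1, at 388656 against 284451 RPM, a log2 ratio of 0.45 that became -0.25 when each site counted the whole read. The arms carried this difference (1.80-fold, 1.79 to 1.81), whereas the pericentromeres were at 0.967-fold (0.963 to 0.971), above 1 when scaled to miRNA reads and with single-site reads (83476 against 68599 RPM). The siR854-related family was 3.09-fold lower at 24 nt (log2 -1.63, and -1.08 with single-site reads). Mutator (2.01-fold), hAT (3.15-fold), Copia (1.62-fold) and Sadhu elements (3.64-fold) were higher, but Mutator at 742 RPM and Copia at 1803 RPM stayed under their wild-type levels of 2258 and 5209. With whole counts the log2 ratios of Mutator, hAT and Copia were 0.38, 0.63 and 0.37.

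Most loci that were lower in ddm1 than in wild type were higher in the double mutant than in ddm1. Of the 46 that were at least 4-fold lower in ddm1 than in wild type, 34 were at least 4-fold higher in the double mutant than in ddm1. Of 470 loci with at least 100 reads in ddm1 or the double mutant, 42 were. These counts are not alike, because the 46 needed 100 reads only in ddm1 or wild type. AT2G04062, for example, had 15 reads in the double mutant, and some of the 34 overlap and share reads. Because the 46 were chosen for a low ddm1 value and ddm1 is also the denominator, part of any excess can arise by construction. Compared with wild type, without ddm1, 24 of the 46 lay within 2-fold in the double mutant. AT5G27606 had 154 RPM in the double mutant, at least 181-fold more than ddm1, AT2G16018 had 138 RPM against 1 read (486-fold, 86.7 to 19256), and AT2G16030 had 409 RPM (160.5-fold, 84.2 to 352). AT4G26730, a methyltransferase-like gene, gave 93.5 RPM, but 10 of its 250.5 reads had a single site because its sequence is shared with other copies. The MADS-box genes AT1G59930 (chromosome 1, 22060924 to 22061516, 99.7% of double mutant reads in coding sequence) and AT1G59920 were low in wild type as well, and AT1G59930 had 145 RPM in the double mutant against 13.5 in wild type and 2.69 in ddm1. AT3G46565, AT5G27603, AT3G29796 and AT5G35923 completed the 10 highest. Summed reads of coding genes were 1.67-fold higher at 21-22 nt and 1.66-fold higher at 24 nt than in ddm1, with 3738 RPM of 21-22 nt from AT3G06435, and of 113 tested coding genes 25 were at least 4-fold higher, 17 lower and 71 between.

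The double mutant against rdr6 addresses the loss of DDM1 where RDR6 is also missing. Of 165 tested loci 37 were at least 4-fold higher and 4 lower. Gene-free windows stood 1.16-fold higher at 21-22 nt (1.15 to 1.17) and 1.23-fold at 24 nt. The siR854-related family was 4.14-fold lower, CACTA elements were 1.60-fold higher (1.44 to 1.78) and Copia elements 0.812-fold (0.751 to 0.878), which turned above 1 when scaled to miRNA reads (log2 0.21). The CACTA direction turned with single-site reads, at 126 RPM in the double mutant against 172 in rdr6. At 24 nt Copia was 3.13-fold and Mutator 3.53-fold lower, while CACTA was 2.00-fold higher. The CACTA difference was smaller with single-site reads, at 1365 RPM in the double mutant against 1083 in rdr6. These log2 ratios shift by 0.51 under the miRNA denominator. Its largest part, miR166a, had 55158 RPM in the double mutant and 121689 in rdr6.

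The remaining lists gave few reads. Among 21 genes of the silencing machinery 3 were measured in each of the first 3 comparisons and 1 in the double mutant over rdr6. AGO1, the slicer loaded with miRNAs, had 40 reads in wild type, 52 in ddm1, 0 in the double mutant and 2 in rdr6, and DCL1 had 22, 37, 6 and 0. Their list median was 0.21 in ddm1 over wild type (54.9th percentile), opposite in sign to their summed reads (0.890-fold, above 1 when scaled to miRNA reads), -1.79 in rdr6 over wild type (7.86th) and -2.23 in the double mutant over ddm1 (43.6th). Of 10 disease resistance genes of the NBS-LRR class, 2 were measured in ddm1 and in rdr6 against wild type. Neither reached 4-fold, but for AT5G43740 in rdr6 the rule could not reach it, because 0 reads were set to 3. AT1G12290 had 30.7, 15.0, 49.7 and 18.3 RPM in wild type, ddm1, the double mutant and rdr6. Nearly all of these reads lay in its untranslated exon, and all were on the strand of the gene. Reads of MIR genes were not left out at genes that overlap them, and such an overlap was not checked here. AT5G43740 had 20.8 and 19.7 reads in wild type and ddm1 and 0 in both rdr6 libraries. None of the 5 genes known as epialleles was measured. Of 7 abundant housekeeping genes, listed as a sign of messenger RNA breakdown, 5 were found in the annotation and 2 were measured in ddm1 against wild type, 1 of them at least 4-fold lower.

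MicroRNAs differed in both directions. miR166a, the most abundant sequence, made up 11.9% of wild-type reads, 9.95% of ddm1, 5.52% of the double mutant and 12.2% of rdr6, and miR165a stayed between 18067 and 21889 RPM. In the double mutant miR168a, which targets AGO1, stood at 1891 RPM against 171 in wild type, 181 in ddm1 and 133 in rdr6, 10.4-fold over ddm1 (9.61 to 11.4). There, miR159a (5914 RPM, 4.06-fold over ddm1), miR162a (1887 RPM, 4.18-fold), miR403 (4264 RPM, 4.62-fold) and miR319a (5786 RPM, 2.92-fold) were higher too. miR158a was lower in all 3 mutants, with 22273 RPM in wild type and 7048 to 9242 in the others. miR163 was higher in all 3 (124 RPM in wild type and 394 to 540.0 in the mutants). Between ddm1 and the double mutant, miR156a was level at 451 RPM (ratio interval 0.928 to 1.08), while miR161.1 differed by 1.73 and miR390a, the trigger of TAS3 siRNAs, by 2.00. All 36 listed sequences had a perfect site in the MIR gene of their name. The TAS3 siRNA tasiARF D7 had 155 reads in wild type and 59 in ddm1, and siR255 of the TAS1 genes had 25 and 10; both had 0 in the double mutant and rdr6, which allows up to 1.12 and 2.03 RPM.

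First bases differed between size classes and libraries. In gene-free windows 24 nt reads began with A in 62.8% of cases in wild type, 62.3% in ddm1, 63.4% in the double mutant and 61.4% in rdr6. The 21 nt reads of these windows began with U in 28.5% of cases in wild type and 37.0% (36.8% to 37.1%) in ddm1, against 30.2% in the double mutant and 27.7% in rdr6. A was their commonest first base in wild type (34.6%), the double mutant (37.0%) and rdr6 (36.6%), and U in ddm1. For 22 nt reads the U share was 32.2%, 42.6%, 36.7% and 33.9%. In coding genes the U share of 21 nt reads was 44.4%, 41.8%, 43.2% and 39.8%.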

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

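The tests of shared copies and of line history for the loci low in ddm1, and those of line history, of reads inside the cluster and of a common scale factor for the RPP5 cluster, were chosen only after the result was seen. With 1 library per genotype, no difference between backgrounds was tested; each value below is a difference of log2 ratios.

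Ratios for the loss of RDR6 had opposite signs in the ddm1 and wild-type backgrounds for several groups. The log2 ratio in ddm1 minus that in wild type was -1.97 for 21-22 nt reads of gene-free windows, -3.28 for pericentromeric windows, -4.04 for undescribed pseudogenes and -7.53 for the siR854-related family. At 24 nt it was -0.24 for pericentromeric windows, which lose the opposite signs under the miRNA denominator and with single-site reads, and -1.88 for the siR854-related family. Coding genes had 1.02 at 21-22 nt and 0.76 at 24 nt, and the NBS-LRR list 2.14 and 3.34. The NBS-LRR value at 21-22 nt includes AT1G12290, whose reads all lay on its own strand and were not checked for an overlapping MIR gene. Ratios for the loss of DDM1 likewise had opposite signs with and without RDR6. The ratio in the rdr6 background minus that in wild type was 0.31 for 24 nt reads of gene-free windows, 0.74 for those on the arms, 0.36 for unassigned pseudogenes and 1.70 for Sadhu elements. At 21-22 nt it was -1.85 for Copia and 0.61 for LINE elements. Under the miRNA denominator the opposite signs vanish for these Copia, LINE, Sadhu and unassigned values, for 24 nt reads of all gene-free windows, for the DDM1 value of undescribed pseudogenes and for the RDR6 value of coding genes at 24 nt. With the whole read counted at every site they vanish for 21-22 nt reads of gene-free windows (-0.23 in wild type and -3.79 in ddm1 for RDR6), and for 24 nt reads of gene-free windows and of unassigned pseudogenes (DDM1). For undescribed pseudogenes (-4.04), coding genes (1.02 and 0.76), the siR854-related family (-7.53 and -1.88) and the NBS-LRR list at 21-22 nt (2.14) the difference has the same size seen from either gene, by arithmetic. The 24 nt reads of the NBS-LRR list, which no planned comparison used, were 6.06-fold higher (5.27 to 6.99) in the double mutant than in wild type. SNC1, RPP4 and RPP5 gave 460 of the 465 RPM there, and their single-site reads showed no excess over wild type (9.34 against 9.59 RPM).

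Of 46 loci at least 4-fold lower in ddm1 than in wild type, 34 were at least 4-fold higher in the double mutant than in ddm1, part of which can arise by construction because both comparisons share the ddm1 library. Reads shared between copies are argued against for the low ddm1 level alone. Of the 34 loci, 33 had at least 50 single-site reads in wild type, and 100% of those were 4-fold lower in ddm1 with such reads. The loci had been chosen as 4-fold lower with shared counts, so a high share was likely beforehand. The higher level in the double mutant was not examined for the set with single-site reads. Scaled to miRNA reads, the median log2 ratio of ddm1 over wild type was -4.20. That denominator adds the same 0.36 to every log2 ratio, which is too little to undo a 4-fold decrease. The loci were chosen for such a decrease, so this outcome was fixed beforehand and does not exclude other faults of the ddm1 library. Loss of RDR6 may keep these loci supplied with siRNAs, or the ddm1 and double mutant lines may have lost and kept them by separate histories, the ddm1 line being labelled as generation F6 and the double mutant without a generation. These cannot be told apart with 1 library per genotype, and the median ratio of rdr6 over wild type at the 34 loci was 0.12.

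SNC1 (AT4G16890), RPP4 (AT4G16860) and RPP5 (AT4G16950), resistance genes of a cluster on chromosome 4 between 9488466 and 9544755, had 151, 146 and 162 RPM of 24 nt in the double mutant, together 460 against 97.1 in ddm1, 61.0 in wild type and 34.6 in rdr6. Reads with every site inside the cluster were 4.61-fold higher than in ddm1 (4.16 to 5.11; 1685 and 482 reads), which argues against copies elsewhere, but single-site reads gave 2.53 (1.25 to 5.39) and no excess over wild type (9.34 RPM against 9.59 in wild type, 3.68 in ddm1 and 11.5 in rdr6), so they leave open which of the genes is the source. A common factor for the whole library is argued against by the median log2 ratio of 945 loci, 0.0930 against 2.24 for shared counts of the 3 genes. The bound set beforehand for the denominator was not met, however, since the 3 genes lay at the 87.3th percentile of those loci and not above the 95th, so a shift shared by a broad set of loci stays open. Loss of RDR6 and a separate history of the lines also cannot be told apart, and rdr6 over wild type gave 0.568 (0.406 to 0.773), a direction that turned with single-site reads.

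The miRNA miR168a was 10.4-fold higher in the double mutant than in ddm1. All 20-22 nt reads on the MIR168 strand, which include the exact sequence, were 6.51-fold higher (6.14 to 6.91). A shift of reads between the exact sequence and its variants of these lengths therefore cannot account for the whole difference. The lower ratio leaves room for a part, and the variants alone were not compared. Leaving miR166a out of the denominator gave 9.95-fold (9.16 to 10.8). That sequence made up 9.95% of ddm1 and 5.52% of double mutant reads, so its removal could shift any ratio only slightly. Its share is too small to account for the ratio, which follows from these percentages and was not a test. GC content was unrelated to the ratios over 18 miRNAs (Spearman rho -0.00521, across sequences that are not independent replicates). No biological explanation was tested.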

How the results depend on the processing

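The family results, the pseudogenes taken in place of windows and the windows without pseudogenes were settings chosen after the data had been seen, and the others were planned. Of 404 alternative values, 202 stayed within the counting interval of the value reported (or, for a count of loci, within 1.5 times of it), 186 moved and 16 reversed in sign, a reversal being counted only where the interval of the reported value excluded 0. Requiring the whole read inside a locus moved none of the values it was applied to, and limiting lengths to 18 to 28 nt changes nothing because the files hold no others. No paired analysis was possible because each genotype had 1 library and no test was made. Depth limits the rdr6 library most, where 3 reads equal 2.03 RPM. Values given here are log2 ratios unless stated, group names stand for pseudogene families, and the cause was not tested unless the setting itself shows it.

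Single-site reads alone gave, for ddm1 over wild type at 21-22 nt, 0.59 for gene-free windows, 1.92 for CACTA, 0.82 for Copia, -2.23 for Mutator, -1.72 for hAT, 4.22 for siR854-related and -0.31 for unassigned (reversed). At 24 nt, ddm1 over wild type here had -0.25 for gene-free windows, 0.54 for CACTA, -2.66 for Copia, -0.66 for LINE, -2.78 for Mutator, -1.92 for hAT, 0.22 for siR854-related and -0.52 for unassigned. Single-site reads alone gave, for rdr6 over wild type at 24 nt, 0.68 for hAT and 0.22 for siR854-related. Single-site reads alone gave, for the double mutant over ddm1 at 21-22 nt, -0.25 for gene-free windows, -2.10 for CACTA, -1.26 for Copia, 0.45 for LINE, 0.58 for Mutator, -6.25 for siR854-related and 0.48 for unassigned (reversed). At 24 nt, the double mutant over ddm1 here had 0.68 for gene-free windows, 0.81 for Copia, 0.39 for LINE, 1.17 for Mutator, 2.07 for hAT, -1.08 for siR854-related and 0.70 for unassigned.

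Whole counts at every site gave, for ddm1 over wild type at 21-22 nt, 4.06 for gene-free windows, 5.21 for CACTA, -0.21 for LINE, -0.0862 for Mutator, -0.11 for hAT, 5.84 for siR854-related and 1.36 for unassigned. At 24 nt, ddm1 over wild type then had 1.36 for gene-free windows (reversed), 2.15 for CACTA, -0.71 for Copia, -0.40 for LINE, -1.36 for Mutator, -0.51 for hAT, 1.24 for siR854-related and 0.77 for unassigned (reversed). Whole counts at every site gave, for rdr6 over wild type at 21-22 nt, -0.23 for gene-free windows (reversed), and at 24 nt 0.12 for gene-free windows, 0.31 for hAT, 0.31 for siR854-related and 0.15 for unassigned. Whole counts at every site gave, for the double mutant over ddm1 at 21-22 nt, -3.79 for gene-free windows, -3.78 for CACTA, -1.50 for Copia, 1.56 for Sadhu, -0.18 for hAT (reversed), -7.36 for siR854-related and -0.99 for unassigned. At 24 nt, the double mutant over ddm1 then had -0.25 for gene-free windows (reversed), -0.14 for CACTA, 0.37 for Copia, 0.71 for LINE, 0.38 for Mutator, 0.63 for hAT, -1.91 for siR854-related and -0.18 for unassigned (reversed).

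Without structural reads the denominator gave, for ddm1 over wild type at 21-22 nt, 2.13 for gene-free windows, 5.42 for siR854-related and 0.16 for unassigned. At 24 nt, ddm1 over wild type here had -0.0681 for gene-free windows, 1.11 for CACTA, -2.28 for Copia, -0.65 for LINE, 0.62 for siR854-related and -0.37 for unassigned. Without structural reads the denominator gave, for rdr6 over wild type at 21-22 nt, 0.0712 for gene-free windows and 0.0604 for unassigned, and at 24 nt 0.18 for gene-free windows, 0.16 for Copia, 0.29 for siR854-related and 0.17 for unassigned. Without structural reads the denominator gave, for the double mutant over ddm1 at 21-22 nt, -1.95 for gene-free windows, and at 24 nt 0.44 for gene-free windows.

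Scaling to miRNA reads gave, for ddm1 over wild type at 21-22 nt, 2.55 for gene-free windows, 3.76 for CACTA, 1.91 for Copia, 0.0537 for LINE (reversed), -1.03 for Mutator, 0.46 for Sadhu, -0.96 for hAT, 5.84 for siR854-related and 0.58 for unassigned. At 24 nt, ddm1 over wild type then had 0.35 for gene-free windows (reversed), 1.53 for CACTA, -1.86 for Copia, -0.23 for LINE, -2.25 for Mutator, 0.13 for Sadhu (reversed), -1.18 for hAT, 1.04 for siR854-related and 0.0535 for unassigned (reversed). Scaling to miRNA reads gave, for rdr6 over wild type at 21-22 nt, 0.15 for gene-free windows, 0.0402 for Copia, 0.10 for LINE, 0.38 for siR854-related and 0.14 for unassigned. At 24 nt, rdr6 over wild type then had 0.26 for gene-free windows, 0.32 for CACTA, 0.24 for Copia, 0.22 for LINE, 0.33 for Mutator, 0.68 for hAT, 0.37 for siR854-related and 0.25 for unassigned. Scaling to miRNA reads gave, for the double mutant over ddm1 at 21-22 nt, -1.67 for gene-free windows, -2.31 for CACTA, -1.66 for Copia, 0.86 for LINE, 0.36 for Mutator, 2.12 for Sadhu, -7.00 for siR854-related and 0.19 for unassigned (reversed). At 24 nt, the double mutant over ddm1 then had 0.72 for gene-free windows, 0.30 for CACTA, 0.96 for Copia, 0.82 for LINE, 1.28 for Mutator, 2.13 for Sadhu, 1.92 for hAT, -1.36 for siR854-related and 0.76 for unassigned.

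Reads of 21 nt alone gave, for ddm1 over wild type, 3.19 for gene-free windows, 4.35 for CACTA, 2.52 for Copia, -0.60 for LINE, -0.45 for Mutator, 6.86 for siR854-related and 0.58 for unassigned. Reads of 21 nt alone gave, for rdr6 over wild type, 0.00949 for gene-free windows, 0.19 for siR854-related and -0.0200 for unassigned. Reads of 21 nt alone gave, for the double mutant over ddm1, -3.09 for gene-free windows, -2.96 for CACTA, -2.27 for Copia, 0.41 for LINE, -0.12 for Mutator, 1.01 for Sadhu, -7.94 for siR854-related and -0.28 for unassigned.

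Reads of 22 nt alone gave, for ddm1 over wild type, 0.92 for gene-free windows, 2.18 for CACTA, 0.0883 for Copia, -0.15 for LINE, -2.53 for Mutator, 3.61 for siR854-related and -0.0431 for unassigned (reversed). Reads of 22 nt alone gave, for rdr6 over wild type, 0.0444 for gene-free windows, -6.70 for TAS and -4.75 for PPR. Reads of 22 nt alone gave, for the double mutant over ddm1, -0.59 for gene-free windows, -1.88 for CACTA, -1.11 for Copia, 0.52 for Mutator, 2.21 for Sadhu, -5.90 for siR854-related and 0.0895 for unassigned (reversed).

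Undescribed pseudogenes in place of windows gave, for ddm1 over wild type at 21-22 nt, 3.72, and at 24 nt -0.14. Undescribed pseudogenes in place of windows gave, for rdr6 over wild type at 21-22 nt, 0.11, and at 24 nt 0.16. Undescribed pseudogenes in place of windows gave, for the double mutant over ddm1 at 21-22 nt, -3.93, and at 24 nt 0.0488.

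Windows without a pseudogene gave, for ddm1 over wild type at 21-22 nt, 0.83, and at 24 nt 0.0127 (reversed). Windows without a pseudogene gave, for rdr6 over wild type at 21-22 nt, 0.00243, and at 24 nt 0.12. Windows without a pseudogene gave, for the double mutant over ddm1 at 21-22 nt, -0.41, and at 24 nt 0.57.

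With single-site reads, 200 gene-free windows were at least 4-fold higher in ddm1 and 179 of them 4-fold lower in the double mutant, against 783 and 735 with shared counts. Whole counts at every site gave 2513 and 1796, a minimum of 20 reads 1542 and 1252, and undescribed pseudogenes 268 and 225, which follows from the number of reads or loci each setting lets in. The 24 nt share without structural reads was 50.2% in wild type, 43.4% in ddm1, 61.9% in the double mutant and 55.0% in rdr6. Counting each distinct sequence once gave 47.5%, 47.1%, 55.1% and 55.0%. The miRNA share taken as 20-22 nt reads on MIR genes was 19.9%, 15.7%, 14.4% and 18.3%. The PPR median with single-site reads was 0.0634 in ddm1 over wild type and -3.40 in the double mutant over ddm1, and with at least 100 reads it was -4.56 in rdr6 over wild type and -5.34 in the double mutant over ddm1.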

Other observations

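The features in this part were chosen after their values were seen, and none was tested. The 6 copies of ONSEN, a Copia retrotransposon known to be activated by heat, had 24 nt siRNAs in wild type, far fewer in ddm1, and in the double mutant close to the wild-type level, least so for AT1G48710 (31.3, 2.26, 21.3 and 30.0 RPM in wild type, ddm1, the double mutant and rdr6). The copy AT1G11265 (chromosome 1, 3781235 to 3785293) had 23.0 RPM in wild type, 2.24 in ddm1, 22.6 in the double mutant and 22.6 in rdr6, and AT3G32415 had 15.4, 1.12, 15.6 and 18.6. Much of their sequence is shared, so the copies are not separate observations. CACTA1 went the same way at 24 nt, with 13.7, 1.49, 11.9 and 15.3 RPM, while its 21-22 nt reads were highest in ddm1 (17.7 RPM). AtMu1 did not, with 148, 0.236, 1.62 and 153 RPM. At RDR2 (AT4G11130, chromosome 4, 6780449 to 6784632), whose product makes the precursors of 24 nt siRNAs, 24 nt reads were 0.639 RPM in wild type, 12.2 in ddm1, 31.0 in the double mutant and 0 in rdr6, where 3 reads equal 2.03 RPM.

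Some less abundant miRNAs also differed. miR396a, which targets growth regulating factors, had 74.8 RPM in wild type, 21.5 in ddm1, 369 in the double mutant and 39.9 in rdr6. The pollen-enriched miR845a had 28.8, 7.65, 2.24 and 22.3 RPM. miR399b, which responds to phosphate supply, was higher in all 3 mutants (54.1, 58.3 and 91.9 RPM in ddm1, the double mutant and rdr6) than in wild type (18.2), and miR398b was highest in ddm1 (18.7 RPM against 2.24 in wild type).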
